A study of Mus musculus with 2 samples.

How the data were processed

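The series holds 2 droplet single-cell RNA-seq libraries from mouse, 1 from WT and 1 from Paqr4 transgenic animals, both made from stromal vascular fraction cells of subcutaneous white fat from which CD45-positive blood cells had been removed by flow cytometry. According to the series text, cells of 3 mice were pooled; it does not say whether 3 per genotype or 3 in all. With 1 library per genotype there is no replicate. No test between genotypes was therefore run, and no p-value, standard error or count of changed genes is given.

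The deposited matrices hold counts, that is, unnormalised unique molecular identifiers (UMIs) per gene and barcode, for every barcode rather than for called cells. The submitters' processing notes name Cell Ranger 7.0.0 and build mm10, whereas the matrix header names Cell Ranger 4; which of them made the files is not given in the sources used here. Each matrix has 32286 features, of which 1 is an added eGFP sequence. The 78 features that shared 38 symbols were summed by symbol, which left 32246 symbols, and 3 symbols of the lists were matched through a RefSeq synonym. Gene positions are from GENCODE M21 (GRCm38), where 32235 of the feature identifiers were found.

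Cells were called from the barcodes at 1000 or more UMIs, 500 or more genes and at most 10% mitochondrial UMIs, and doublets called by Scrublet (scanpy 1.11.5, anndata 0.12.19) in each library were removed. Counts of both libraries were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 nearest neighbours gave a shared-neighbour graph that was clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5 with seed 1, with no correction between libraries. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

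Clusters were named from marker lists of 18 cell types that were fixed before the data were examined. A marker counted as on at 25% or more of its highest level over clusters and at 20 or more UPM (UMIs per 1000000 UMIs of the class); a class needed at least 50% of its markers on, and at least 3. Progenitor clusters were named Dpp4-like, Icam1-like or F3-like when at least 3 markers of that subclass lay 1.5-fold or more above the other progenitors. The marker names themselves were fixed, but these thresholds, and the rule that left a cluster unnamed when markers of another class led its 10 top genes, were chosen after the clusters had been seen. Differences between clusters in their defining genes are not reported as results, but some of these genes, such as C7, Sfrp2 and Pi16, are compared between the libraries. Because genes that differ between the libraries can shape clusters, shares are also given from a clustering without the 284 genes that differed by 1 log2 unit or more in progenitors.

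Within a class, UMIs were summed per library and divided by the class total to give UPM. Each level carries an exact Poisson interval, each share of cells an exact Clopper-Pearson interval, and each ratio (Paqr4 transgenic over WT, as log2) an exact conditional binomial interval, all at 95%. These intervals cover counting error only, and say nothing about how mice vary. Those of levels and ratios also leave out how UMIs vary between cells, so they are too narrow where few cells hold many UMIs. A gene at 0 UMIs in a library was set to a floor of 3 UMIs for the ratio, which is then a bound. Total UMIs per library were 44145257 for WT and 43084906 for transgenic, of which 28418301 and 28230354 lay in the cells used. The floor of 3 UMIs corresponds to 0.116 UPM in WT and 0.113 UPM in transgenic progenitors.

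Classes with at least 200 cells in each library were compared, namely all progenitors, the Icam1-like cells and cluster 2. The named genes follow a rule set before the data were examined: Paqr4, the 12 genes with the highest and the 12 with the lowest ratio in progenitors among those at 50 UPM or more in a library, up to 4 members with the largest ratio in each list among those at 10 UPM or more, and the 5 highest and 5 lowest in each other class. 1 of the genes that the rule picked is not reported here. Predicted genes named Gm or Rik, mitochondrial, sex-linked and haemoglobin-type genes were left out of the highest and lowest. The genes of depot position and X escape were written down before their values were looked up. The other genes outside this rule that are named below were chosen after values had been seen.

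The 27 gene lists, also fixed beforehand, were the PAQR family, ceramide synthesis, ceramide consumption and sphingosine phosphate, adipogenesis, extracellular matrix, matrix remodelling, TGF-beta and BMP signalling, Wnt signalling, inflammatory cytokines and NF-kB, interferon response, complement and acute phase, dissociation and immediate early genes, heat shock, ER stress and unfolded protein response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, oxidative stress response, senescence and p53, proliferation, thermogenic and beige genes, insulin and IGF signalling, the fibro-inflammatory progenitor list, mitochondrially encoded genes, nuclear oxidative phosphorylation, nuclear retained RNA, sex-linked genes, and free RNA from blood and contaminating tissue. For each list the median log2 ratio of its members at 10 UPM or more was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these 2 libraries and is not a p-value, because genes are not independent replicates.

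The alternatives were looser cell limits (500 UMIs, 200 genes, 20% mitochondrial), stricter limits (2000, 1000 and 5%), doublets kept, resolutions 0.3 and 1.0, each library clustered on its own, expression centred per library, and differing genes left out of the clustering. For ratios there were also median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, subtraction of the profile of barcodes with 50 or fewer UMIs at 10%, thinning of each cell to 5000 UMIs, equal weights for the progenitor subclasses, and list floors of 50 UPM or none. For the test of subclass shares, cells were resampled 1000 times within each subclass and library. Thinned cells for the shares, and cluster 1 alone for the Icam1-like ratios, were added after seeing the data. No replicate could be left out, and no pairs or other splits of samples could be formed with 1 library per genotype.

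The ratios were tested on simulated data. Poisson sums were drawn for the 3611 progenitor genes at 50 UPM or more, with 200 genes given folds from 0.25 to 4. The 95% intervals held the true fold for 94.8% of genes, and all 200 changed genes (100%) had intervals on the right side of no difference. Because the draws follow the same counting model as the intervals, this checks the calculation only. It cannot show how well the intervals hold for real cells, whose UMIs vary more. A simulated list of 20 raised genes reached percentile 100, and 20 genes left alone gave percentile 72.9.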

Results

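Single-cell transcriptomes were read from CD45-negative stromal vascular cells of mouse subcutaneous white fat, in 1 WT library and 1 library from mice carrying a Paqr4 transgene. The stromal vascular fraction is what is left of fat after the adipocytes have been removed, and it holds the progenitors that form new adipocytes. The WT library held 44145257 UMIs and gave 1328 cells, with medians of 21612.5 UMIs and 4650 genes per cell. The transgenic library held 43084906 UMIs and gave 1521 cells, with medians of 18711 UMIs and 4480 genes. Haemoglobin transcripts took 28.2% of all WT UMIs and 29.1% of all transgenic UMIs. Each genotype had 1 library, so no difference below has been tested. Every interval is a 95% interval for counting error only, except where cells are said to be resampled.

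The libraries also differed in sex. Xist, the RNA that silences an X chromosome in female cells, had a UMI in 94.3% of WT progenitors (92.8 to 95.6, Clopper-Pearson) and in 0.219% of transgenic ones (0.0453 to 0.640). Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had a UMI in 2.03% of WT progenitors (1.29 to 3.03) and in 94.1% of transgenic ones (92.7 to 95.3). Xist stood at 957 UPM in WT and 0.151 UPM in transgenic progenitors, and its antisense RNA Tsix at 46.8 and 0.0377 UPM. Uty, with 0 UMIs in WT against a floor of 3 UMIs, was at least 808-fold higher in the transgenic library. The labels give no sex. Genotype and sex therefore differed together between these libraries, and this holds for every gene group below.

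The first comparison asked whether the target gene itself differed. Paqr4, a member of the progestin and adipoQ receptor family, was detected at a low level in progenitors of both libraries. It stood at 7.84 UPM (6.80 to 8.996, exact Poisson) in WT progenitors, from 203 UMIs, and at 9.43 UPM (8.30 to 10.7) in transgenic ones, from 250 UMIs. The transgenic level was 1.203-fold the WT level (0.996 to 1.46; log2 0.27, from −0.01 to 0.54), so no difference was detectable at this depth, and a ratio above 1.46 lay outside the interval. Reads of the transgene would be counted here only if they fall within the annotated gene, and the labels do not give the 3′ end of the transgene. The labels name no promoter either, so which cells express the transgene is not known. Paqr4 (ENSMUSG00000023909) lies on the minus strand of chromosome 17, at 23736186 to 23740867 in GRCm38.

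Paqr4 UMIs occurred in 15.2% of WT progenitors (13.1 to 17.4) and 15.9% of transgenic ones (14.0 to 18.0), at medians of 22694 and 19327 UMIs per cell. With every cell thinned to 5000 UMIs the shares were 3.70% (2.66 to 5.01) and 5.25% (4.11 to 6.60). Endothelial cells, which were shallower at 9417 and 7468 UMIs, carried one in 10.7% and 9.78% of cells, and by level stood at 13.7 UPM (7.48 to 23.0) and 13.4 UPM (6.13 to 25.5). Barcodes with 50 or fewer UMIs, which sample free RNA, held 4.82 UPM (2.75 to 7.82) in WT and 5.56 UPM (2.78 to 9.95) in transgenic. Among progenitors, Icam1-like cells had 12.7 and 12.6 UPM of Paqr4 (log2 −0.01, from −0.45 to 0.45), but clustering each library on its own moved the Icam1-like value to 0.50. Cluster 2, defined below, had 5.15 UPM in WT from 40 UMIs and 9.75 UPM in transgenic from 60 UMIs (log2 0.92, from 0.32 to 1.54).

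The second comparison asked which cells made up each library. Progenitors, marked by Pdgfra, Dcn and collagen transcripts, were 85.5% of WT cells (83.5 to 87.3) and 89.9% of transgenic cells (88.2 to 91.3). Endothelial cells were 7.76% of WT cells (6.37 to 9.33) and 6.05% of transgenic cells (4.90 to 7.37). Lymphatic and blood endothelial cells are not compared, because the lymphatic cluster (7) had 4 markers of each kind among its 10 top genes. With the 284 genes that differed between the libraries left out of the clustering, progenitors were 82.3% and 87.6% of cells, and endothelial cells 7.30% and 5.33%. Mesothelial cells (12 in WT and 11 in transgenic), pericytes or smooth muscle (12 and 6), epithelial cells (9 and 6) and Schwann cells (6 and 3) were few, and 3 clusters stayed unnamed (10, 11 and 15).

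Among progenitors, the Dpp4-like population, known as interstitial progenitors at the root of the lineage, was the smaller one in the transgenic library. Dpp4-like cells (cluster 3) were 21.3% of WT progenitors (19.0 to 23.8) and 13.4% of transgenic ones (11.6 to 15.3), a ratio of 0.628. Icam1-like cells, known as committed preadipocytes (clusters 1 and 9), were 22.9% of WT (20.5 to 25.5) and 32.8% of transgenic progenitors (30.4 to 35.4), a ratio of 1.43. F3-like cells (cluster 4), named after the F3 (CD142) cells described as regulators of adipogenesis, were 9.69% (8.03 to 11.6) and 15.7% (13.8 to 17.7), a ratio of 1.62. The remaining 46.1% of WT and 38.1% of transgenic progenitors met the threshold of no subclass. They form cluster 2 (317 and 284 cells), cluster 5 (175 and 131) and cluster 6 (31 and 106).

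The Dpp4-like share kept its direction under all 9 alternative ways of calling and clustering cells, with ratios from 0.502 to 0.695. Without the 284 differing genes it was 21.6% in WT and 13.5% in transgenic progenitors, and Icam1-like cells were 20.3% and 30.9%. F3-like cells were then 20.7% and 24.6%. Clustering each library on its own turned the directions of the Icam1-like share, to 43.5% in WT and 31.3% in transgenic, and of the F3-like share, to 27.8% and 9.58%. The subclass markers were also read over all progenitors, without cluster borders. The median of 11 Dpp4-like markers was −0.19 (percentile 0.15 among random lists), with 9 lower and 2 higher (Dpp4 −1.01, Pi16 −0.56, but Ace 0.72). That of 12 Icam1-like markers was 0.21 (percentile 98.9), with 8 higher and 4 lower (Col4a1 0.49, but Icam1 itself −0.35 and Apoe −1.07). That of 10 F3-like markers was 0.33 (percentile 99.96), with 8 higher and 2 lower (Fmo2 0.97, Meox2 0.80). With equal weights for the subclasses, the Dpp4-like median turned to 0.18 and the Icam1-like median to −0.12.

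**Figure D1:**
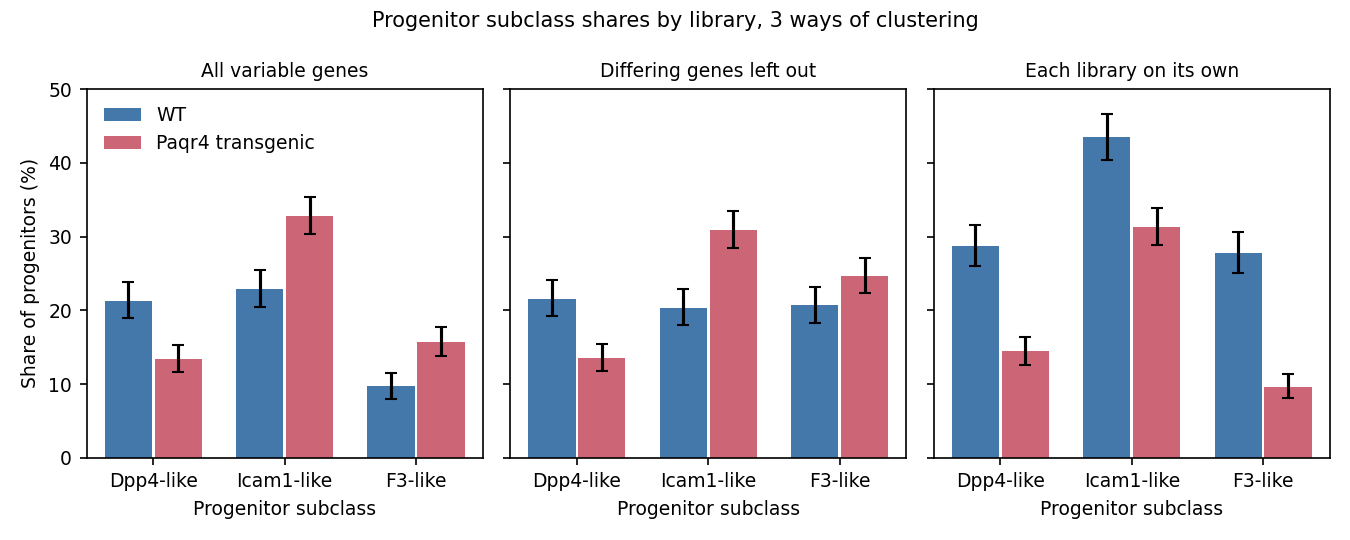
Share of progenitors (percent, y axis) in each subclass (x axis) for WT and Paqr4 transgenic libraries, with all variable genes, with the 284 differing genes left out, and with each library clustered on its own; error bars are 95% Clopper-Pearson intervals for counting error only. The Dpp4-like share is lower in the transgenic library in all 3 panels, while the Icam1-like and F3-like shares turn in the last.

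The third comparison asked which genes differed within progenitors (1135 WT and 1367 transgenic cells). C7, a terminal complement component, was 6.55-fold higher in the transgenic library, at 54.7 UPM in WT and 358 UPM in transgenic (log2 2.71, from 2.63 to 2.79). Igfbp3, which binds insulin-like growth factors, was 8.26-fold lower, at 60.4 and 7.32 UPM (log2 −3.05, from −3.27 to −2.83). For C7, 5 cells held 37.1% of the WT UMIs. For Igfbp3, 5 cells held 32.1% of the WT UMIs and 5 cells 38.1% of the transgenic UMIs. Sfrp2, a secreted Wnt modulator, was 7.85-fold lower, at 53.3 and 6.79 UPM (log2 −2.97, from −3.21 to −2.75). The median ratio over the 3610 genes at 50 UPM or more with UMIs in both libraries was 0.08.

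Higher in the transgenic library by rule were also Sult1e1, which inactivates oestrogens (log2 4.68, from 4.38 to 5.00), the serine protease inhibitor Serpine2 (2.35, from 2.18 to 2.51), the collagen Col8a1 (2.17), Csmd1 (1.82), the matrix protein Hmcn2 (1.50), Cilp (1.47), the protease Adamts6 (1.43), the exchange factor Vav3 (1.40) and Ccn2, a matricellular target of TGF-beta (1.26). In WT, 90.2% of the Sult1e1 UMIs came from 5 cells; a Sult1e1 UMI was seen in 1.23% of WT and 17.8% of transgenic progenitors. Likewise 5 cells held 59.2% of the WT UMIs of Col8a1, and 43.9% of the WT and 34.2% of the transgenic UMIs of Csmd1. The immunoglobulin genes Igkc (8.48) and Igha (7.86) headed the list by size. However, 99.7% and 99.6% of their transgenic UMIs lay in 5 cells, and Igkc turned to −2.95, and Igha stood at 0.34, when each library was clustered on its own. Csmd1 then stood at 0.72. Sfrp2 and C7 are among the top genes of the Dpp4-like and F3-like clusters, whose shares differed. With equal weights for the subclasses C7 stood at 2.10 and Sfrp2 at −2.58. With cells resampled these ran from 1.42 to 2.85 and from −3.08 to −2.10, wider than the counting intervals. Igfbp3 stood at −2.98 with equal weights and ran from −3.85 to −2.15 with cells resampled.

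Lower in the transgenic library were the neural adhesion genes Lsamp (−2.63, from −2.77 to −2.49), Nrxn3 (−2.12) and Opcml (−1.35), the matrix gene Thsd4 (−2.05), the interleukin-4 receptor Il4ra (−1.86), the zinc finger factor Zbtb16 (−1.68), Fam155a (−1.36), the lipase Daglb (−1.30), the imprinted gene Peg3 (−1.29) and the carboxylesterase Ces1d (−1.29). Zbtb16 was among the more abundant of these, at 931 UPM in WT and 290 UPM in transgenic, and Opcml stood at 921 and 362 UPM. All 24 genes kept their direction with equal subclass weights and 19 kept at least 1 log2 unit; Cilp, at 0.59, was the lowest in size. Sex-linked genes were left out of the 24 by rule. Autosomal genes had a median of 0.08, X-linked genes 0.07, and 5 genes known to escape X inactivation (Kdm6a, Eif2s3x, Ddx3x, Kdm5c and Utp14a) −0.68.

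**Figure D2:**
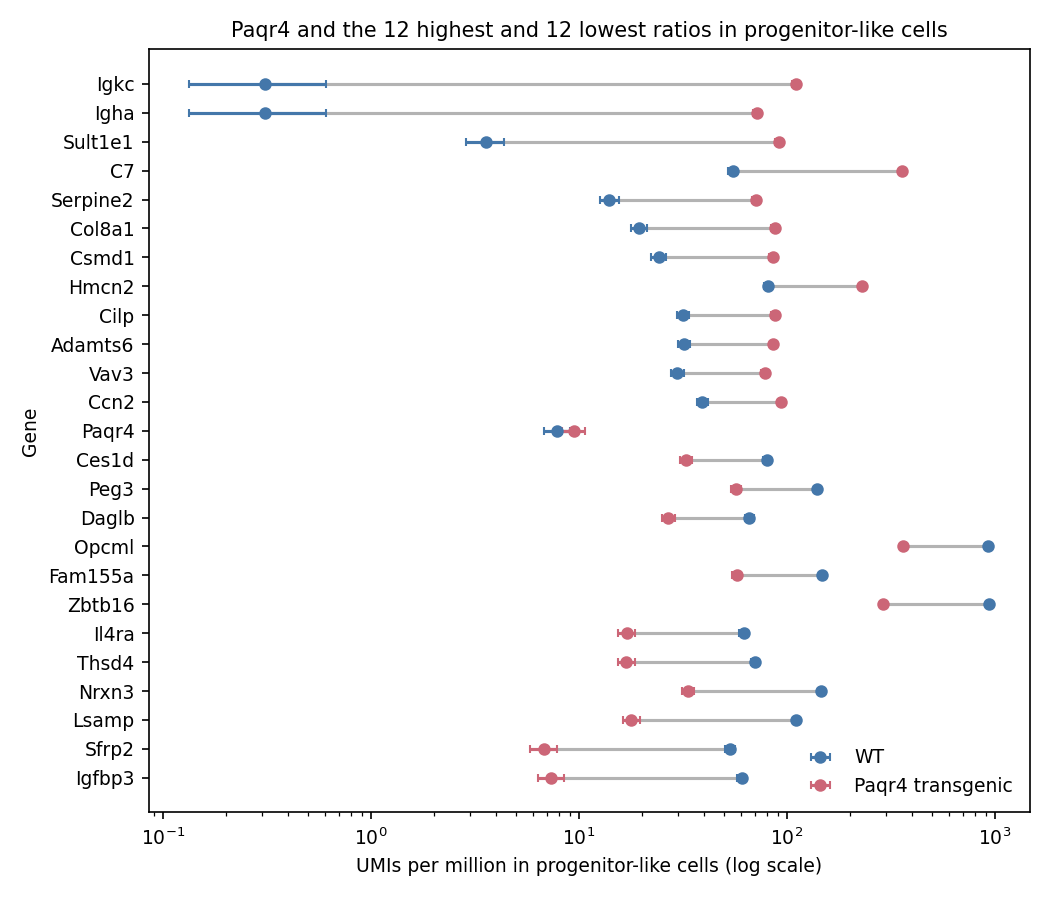
UMIs per 1000000 UMIs in progenitors (x axis, log scale) of Paqr4 and of the 12 genes with the highest and the 12 with the lowest ratio (y axis), in the WT and Paqr4 transgenic libraries; points are sums over 1 library each, and bars are exact 95% Poisson intervals for counting error only. C7 lies at 54.7 UPM in WT and 358 UPM in transgenic, Igfbp3 at 60.4 and 7.32 UPM, and Paqr4 at 7.84 and 9.43 UPM; nearly all transgenic Igkc and Igha UMIs lie in 5 cells.

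The fourth comparison read the fixed gene groups in progenitors. Cholesterol and fatty acid synthesis genes were higher together in the transgenic library. Of 22 measured members, 21 lay above no difference and 11 at 1.5-fold or more, with a median of 0.60 (0.53 to 0.68), above all 10000 random lists. Sterol enzymes in the group included Fdft1 at 1.97 (3.36 UPM in WT and 13.2 UPM in transgenic), Cyp51 at 1.46 and Msmo1 at 1.44. The group stood at 0.27 in Icam1-like cells, though at 0.49 in cluster 1 alone and 0.59 at resolution 0.3, and at 0.70 in cluster 2, where Sqle reached 2.50.

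Inflammatory cytokine and NF-kB genes were lower together, with 20 of 23 members below no difference and a median of −0.35 (−0.36 to −0.31), below all random lists. The pentraxin Ptx3 stood at −1.10, the hyaluronan synthase Has2 at −0.87, and the chemokines Cxcl12 and Cxcl2 at −0.79 and −0.73. The median was −0.19 in cluster 2 and −0.17 with equal subclass weights. In Icam1-like cells it was 0.09 and turned with the clustering, to −0.22 at resolution 0.3 and −0.86 with each library clustered on its own. Interferon response genes had a median of −0.17 (−0.22 to −0.13), with 21 of 27 lower; Ifitm1 stood at −1.29, Ifit1 at −0.72 and Irgm1 at −0.66, but Igtp at 0.58. Their medians were −0.42 in Icam1-like cells and −0.40 in cluster 2, whereas equal subclass weights gave −0.01. The medians of both groups thus moved with the weights of the subclasses.

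Below the central 95% of random lists also lay Wnt signalling at −0.14 (percentile 0.03; Sfrp2 as above, Dkk2 −0.82, but Wnt5b 0.96 and Dact1 0.67), insulin and IGF signalling at −0.14 (0.02; Igfbp3 as above, Igfbp5 −0.63, Pik3r1 −0.48), the oxidative stress response at −0.12 (0.08; the metallothioneins Mt2 −0.74 and Mt1 −0.63, but Gpx3 0.55) and the fibro-inflammatory progenitor list at −0.11 (1.24; Fn1 −0.48, Il33 −0.42, but Cd9 0.38). The fibro-inflammatory median turned to 0.18 with equal weights, and the oxidative stress median was −0.00413 among members at 50 UPM or more. Above that range lay heat shock at 0.21 (99.4; Hspb1 1.00, Hsp90aa1 0.50), the ER stress and unfolded protein response at 0.17 (98.0; Calr 0.56, Manf 0.55, Hspa5 0.47) and extracellular matrix at 0.13 (99.7). The matrix genes went both ways, with Bgn at 0.74 and Fbln2 at 0.62 against Postn at −0.995 and Lum at −0.71. The list of free RNA from blood and contaminating tissue had a median of −0.48 (0.01), with Hbb-bt at −0.82 and Hba-a1 at −0.48. It turned to 0.38 when cells were thinned.

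The groups tied most closely to PAQR4 lay inside the central 95%. The 3 of 11 PAQR family members that passed the list floor had a median of 0.23 (percentile 87.7). They were Paqr8 at 0.35, Adipor1 at 0.23 and Adipor2 at 0.16. Ceramide synthesis stood at 0.17 (89.9); its sphingomyelinase Smpd3 was at −0.98 (291 UPM in WT and 147 UPM in transgenic), while Cers4 and Cers5 were at 0.38 and 0.35. Ceramide consumption and sphingosine phosphate genes stood at 0.14 (74.7), with the receptor S1pr3 at 1.71 and Ugcg, which makes glucosylceramide, at −0.44. Adipogenesis genes had a median of 0.04 (37.7), with 8 of 14 members above and 6 below no difference; Plin2 stood at 0.51, Cebpb at −0.48 and Pparg at 0.00.

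**Figure D3:**
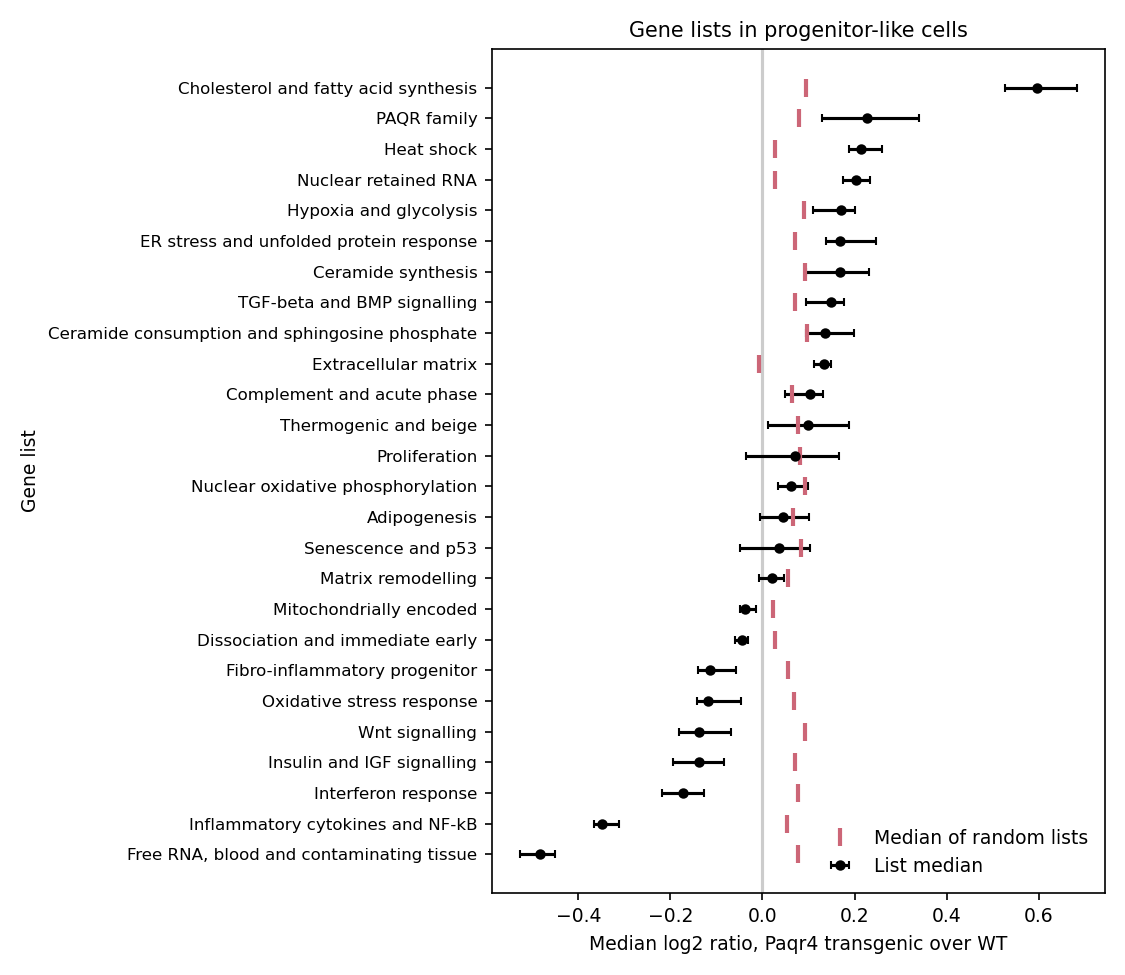
Median log2 ratio, Paqr4 transgenic over WT (x axis), of each gene list (y axis) in progenitors, with bars for 95% counting error; red ticks mark the median of 10000 random lists matched on size and expression. Cholesterol and fatty acid synthesis lies highest at 0.60, and the free RNA list and inflammatory genes lie lowest at −0.48 (0.38 with thinned cells) and −0.35.

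The other lists also lay inside the central 95%. TGF-beta and BMP signalling stood at 0.15 (percentile 94.5; Inhbb 1.64, Fst −0.84), hypoxia and glycolysis at 0.17 (94.3; Pfkp 0.32, Vegfa −0.36) and nuclear retained RNA at 0.20 (95.6; Neat1 0.34, Malat1 0.30). Acta2, at 2.97, is a member of the TGF-beta and thermogenic lists, and 82.7% of its transgenic UMIs came from 5 cells. Complement and acute phase genes stood at 0.10 (71.7; Hp 2.98, with 47.9% of its WT UMIs in 5 cells, Serpina3n 0.72, C1s1 −0.52), matrix remodelling at 0.02 (29.3; Mmp2 −0.46) and dissociation and immediate early genes at −0.04 (10.7; Dusp6 1.09, Zfp36 −0.56). Senescence and p53 genes stood at 0.04 (21.9; Plk2 0.90), proliferation at 0.07 (44.2; Tubb5 0.51), thermogenic and beige genes at 0.10 (57.3; Slc6a8 0.18), mitochondrially encoded genes at −0.04 (23.6; mt-Nd3 −0.51) and nuclear oxidative phosphorylation at 0.06 (19.6; Cox5a 0.48). Only 6 of 24 proliferation members and 4 of 16 thermogenic and beige members passed the list floor in progenitors. The medians of both lists therefore do not cover their other members, and whether those differed was not tested. The sex-linked list has no median, since its members were left out of the gene groups and are given above.

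The last comparison repeated the gene ratios within Icam1-like cells (260 WT and 449 transgenic) and within cluster 2 (317 and 284), a progenitor group that met the threshold of no subclass. In both, C7 and Serpine2 were higher, and Lsamp and Igfbp5 lower, in the transgenic library. In Icam1-like cells C7 stood at 5.98 UPM in WT and 202 UPM in transgenic (log2 5.08, from 4.58 to 5.62). Lsamp stood at 98.6 and 1.87 UPM (−5.72, from −6.54 to −5.01). The long non-coding RNA Morrbid (2.37), Serpine2 (1.64), the angiotensin-converting enzyme Ace (1.63) and Dnaja4 (1.52) were also higher. Igfbp3 (−4.56), Igfbp5 (−3.67), Trhde (−3.10) and Fam13a (−2.74) were lower. Insulin and IGF signalling genes had a median of −0.48 in these cells (percentile 0, with 13 of 18 lower), including Pik3r1 at −1.05 and Irs1 at −0.78. Clustering each library on its own brought that median close to no difference, at −0.0626, and Pik3r1 to −0.24, and Irs1 stood at −0.38 at resolution 0.3.

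In cluster 2, Sult1e1 stood at 3.23, Serpine2 at 3.15, Csmd1 at 2.88, C7 at 2.55 (34.0 and 199 UPM) and Cilp at 1.95. Lsamp stood at −3.01, Igfbp5 at −2.57, Nrxn3 at −2.43, Fgf12 at −2.14 and Zbtb16 at −1.82 (763 and 216 UPM). In this cluster 5 cells held 97.4% of the WT UMIs of Sult1e1, and 72.6% and 53.6% of the transgenic UMIs of Csmd1 and Cilp. Cluster 9, which held 39 WT and 9 transgenic Icam1-like cells, moved some Icam1-like values by more than their counting error. With cluster 1 alone, an alternative chosen after seeing the data, Lsamp stood at −4.83, Igfbp3 at −3.57 and Serpine2 at 2.26, while C7 stood at 4.94. The sizes also moved with the clustering, though not the directions: C7 stood at 2.38 at resolution 0.3, and clustering each library on its own gave Lsamp −2.30, Igfbp3 −1.21 and Fam13a −1.21.

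Transcripts of the exocrine pancreas and genes of visceral fat position were found in both libraries. Cluster 11 held 25 WT and 5 transgenic cells with digestive enzyme transcripts, and acinar genes took 0.963% of all WT and 0.314% of all transgenic UMIs. In progenitors, Wt1, a factor of visceral fat and mesothelium, stood at 497 UPM in WT (489 to 506) and 380 UPM in transgenic (373 to 387), against 1.96 and 1.49 UPM in endothelial cells. Tcf21 stood at 133 and 117 UPM and Gata6 at 51.3 and 57.4 UPM. Tbx15, a factor of subcutaneous fat, stood at 1.12 and 2.26 UPM, and Shox2 at 0.193 and 0.151 UPM. Summed over the chosen genes, the visceral group had 696 and 567 UPM and the subcutaneous group 10.7 and 13.6 UPM. Wt1 was the largest part of the visceral sum, and a Wt1 UMI was seen in 79.6% of WT and 75.1% of transgenic progenitors. Visceral Gata4 had 0 UMIs in both libraries, and Barx1 (0.270 and 0.151 UPM), Nkx2-5 (0 and 0.113) and Nkx3-2 (0.425 and 0.189) lay below subcutaneous Hoxc9 (4.33 and 4.94). The labels name subcutaneous fat as the source.

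**Figure D4:**
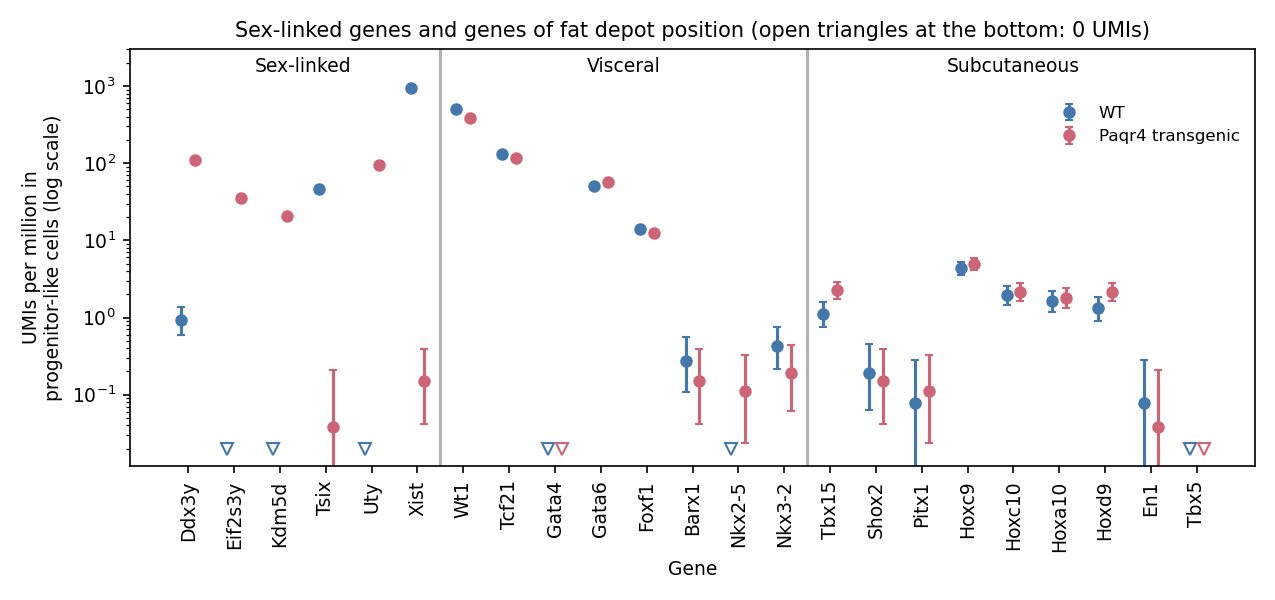
UMIs per 1000000 UMIs in progenitors (y axis, log scale) of sex-linked genes and of genes of visceral and subcutaneous fat position (x axis) in the WT and Paqr4 transgenic libraries; bars are exact 95% Poisson intervals for counting error, some of which run below the axis, and open triangles mark 0 UMIs. Xist is at 957 UPM in WT, the Y-linked genes are in the transgenic library, and Wt1 is at 497 and 380 UPM.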

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

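The tests of swapped reads, of free RNA in the pancreas pattern, of sex and of subclass shares were chosen only after the result was seen. So were the shares from thinned cells. The equal weights themselves and the other tests were chosen before.

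The eGFP feature, which no comparison uses, had 4 UMIs over all barcodes of the Paqr4 transgenic library, all outside the cells used, and 0 in WT. Igkc, Igha and Jchain, of antibody-secreting cells, had 15.21 UMIs per 1000000 in transgenic barcodes not used as cells, above the 1.34 in WT. Cilp was higher in the transgenic library in cluster 2 (1.95) and lower in Icam1-like cells (−0.67), a gap of 2.617 log2 units whose difference was not tested, and 5 cells held 53.6% of its transgenic UMIs in cluster 2.

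Exocrine pancreas transcripts were found in both libraries, beside progenitors with Wt1 and Tcf21. Reads swapped from another library are argued against, because acinar-like cells held at least 47.2% of the median UMIs of progenitors. Free RNA alone is argued against by the share of acinar genes in acinar-like cells (25 in WT and 5 in transgenic). The median of that share was at least 12.19 times the share in free RNA, but these cells were grouped by such genes. Cells with acinar genes above 30% of their UMIs were also counted. The 23 in WT argue against free RNA alone, but the 5 in transgenic were fewer than that test required. By that count the transgenic library stays undecided. Tissue next to the pancreas or visceral fat in the dissected samples is a candidate explanation, because the summed visceral genes, of which Wt1 was the largest part, stood at least 41.6 times above the subcutaneous ones in progenitors of both libraries; that test was chosen before its values were seen. Wt1 was not confined to a few cells, with a UMI in 79.6% of WT and 75.1% of transgenic progenitors. No biological explanation was tested, and the labels name subcutaneous fat.

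Icam1-like cells made up a larger share of transgenic progenitors. Clusters drawn by the strongly differing genes alone are argued against, since the ratio of shares was 1.523 without those genes, and a difference in depth is argued against by a ratio of 1.92 in thinned cells. The way the class is bounded stays open, because clustering each library on its own gave 0.720. Sex and genotype cannot be told apart, since Xist was in 0.2195% of transgenic progenitors and no library holds the other pairing. Whether the share follows the transgene therefore stays open and untested, and so does a difference in the dissected tissue.

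C7, Igfbp3, Sfrp2, Zbtb16 and other genes differed within progenitors. Free RNA is argued against as the whole cause for these genes, because all 24 kept at least 1 log2 unit after its profile was subtracted at 10%. Unequal subclass shares are argued against as the whole cause for most of these genes. With equal weights all 24 kept their direction, and 21 had 95% intervals off 0 when cells were resampled. The 24 were picked as the most extreme ratios of these data, and resampled cells do not stand for mice. The 19 that kept that size fell just short of the share required by a test of size, which stays undecided. Unequal shares stay open for Igkc, Igha and Cilp and as part of the size of other genes. Sex cannot be told apart from genotype either, with Y-linked UMIs in 2.026% of WT progenitors against 94.1% of transgenic ones. A transgene effect, a sex effect, a difference between the mice and a difference in the dissected tissue remain open. The last was not tested for these genes, but acinar genes took 0.963% of all WT and 0.314% of all transgenic UMIs.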

How the results depend on the processing

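The shares from thinned cells and the values from cluster 1 alone were chosen only after the result was seen; every other alternative was chosen before the data were examined. The Paqr4 ratio in all progenitors kept its direction and stayed inside its counting interval in all 13 alternatives, from 0.17 to 0.46. Some of these could hardly move ratios in progenitors, including those of the named genes counted below. At resolution 1.0 the progenitors were again 1135 WT and 1367 transgenic cells, with the same ratios. Keeping doublets added back only 1 WT and 4 transgenic cells, and the changes of scaling shift these genes alike. In Icam1-like cells (−0.01) the Paqr4 ratio ran from −0.0475 to 0.50, below 0 in 5 alternatives and above in 8. It left its interval when each library was clustered on its own. The Dpp4-like share was lower, and the progenitor share higher, in the transgenic library in all 9 ways of calling and clustering cells. Icam1-like cells were higher in 8 and lower in 1, with ratios from 0.720 to 1.92, but only 1.09 at resolution 1.0. F3-like cells were higher in 7 and lower in 1, with ratios from 0.345 to 1.78 and no F3-like class at resolution 0.3. Their ratio was close to no difference at 1.05 with centred expression, 1.05 in thinned cells and 1.07 with looser limits. Of 88 share values, 52 stayed inside their counting interval; so did 1341 of 1596 values of named genes and 345 of 432 list medians in progenitors, and 336 of 440 values in the other classes. The cholesterol and fatty acid synthesis median stayed between 0.40 and 0.63. Depth leaves the Paqr4 ratio an interval from −0.01 to 0.54. With 1 library per genotype no replicate could be left out. No paired analysis was possible because each genotype has a single library.

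Shares that left their interval are given for WT and then transgenic. The cause was not tested unless stated. Progenitors were 82.5% and 86.7% of cells with expression centred per library, 82.3% and 87.6% without the differing genes, 76.9% and 87.1% with each library on its own, 75.6% and 84.8% with looser limits, 88.4% in WT with stricter limits, and 87.5% in transgenic at resolution 0.3. Endothelial cells were 4.97% and 4.87% with each library on its own, and 4.33% and 1.31% in thinned cells, where the shallower cells are left out by construction. Dpp4-like cells were 28.7% of WT progenitors with each library on its own. Icam1-like cells were 45.6% and 55.3% at resolution 0.3, 36.04% and 39.1% at resolution 1.0, and 13.2% and 25.4% in thinned cells. They were 29.3% in transgenic with centred expression, and in WT 20.3% without differing genes, 43.5% with each library on its own, 20.5% with looser and 25.6% with stricter limits. F3-like cells were 26.8% and 28.3% with centred expression, 20.7% and 24.6% without differing genes, 27.8% and 9.58% with each library on its own, 23.2% and 24.8% with looser limits, and 31.7% and 33.2% in thinned cells.

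List medians in progenitors moved as follows. Median-of-ratios scaling shifts all genes by 0.08 and gave extracellular matrix 0.0506, Wnt −0.22, inflammatory −0.43, interferon −0.26, heat shock 0.13, ER stress 0.0860, cholesterol and fatty acid synthesis 0.51, oxidative stress −0.20, insulin and IGF −0.22, fibro-inflammatory −0.20 and free RNA −0.57. Nuclear oxidative phosphorylation reversed to −0.0206. Equal subclass weights gave matrix 0.0768, Wnt −0.29, inflammatory −0.17, interferon −0.0106, heat shock 0.15, insulin and IGF −0.20 and free RNA −0.22; fibro-inflammatory reversed to 0.18, complement to −0.0333, Dpp4-like markers to 0.18 and Icam1-like markers to −0.12. Thinned cells gave matrix 0.11, inflammatory −0.37, interferon −0.25, oxidative stress −0.0337, fibro-inflammatory −0.0503 and free RNA 0.38, a reversal. With each library on its own, inflammatory stood at −0.37, fibro-inflammatory at −0.16 and free RNA at −0.38, while mitochondrially encoded genes reversed to 0.000126. Members at 50 UPM or more gave interferon −0.22 and cholesterol 0.40, with oxidative stress at −0.00413. With no floor, ER stress stood at 0.25 and cholesterol at 0.52, while complement reversed to −0.0334 and thermogenic genes to −0.53. The free RNA list stood at −0.41 without differing genes, −0.25 with centred expression, −0.76 with looser limits and −0.40 at resolution 0.3. It reversed to 9.81 when free RNA was subtracted, which by construction removes its haemoglobin members and leaves Igkc.

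Among genes in progenitors, Igkc reversed to −2.95 with each library on its own. In thinned cells Adipor2 reversed to −0.0211, Pcna to 0.0213, Hba-a2 to 0.38 and Hba-a1 to 0.48. Equal weights reversed Mmp3 to −0.0140, Ebf2 to 0.105 and Ccn3 to 0.0521, and subtraction of free RNA reversed mt-Nd1 to −0.00371. In Icam1-like cells the fibro-inflammatory median (0.21) reversed to −0.26 at resolution 1.0 and −0.85 with each library on its own. The inflammatory median there reversed to −0.22 at resolution 0.3, −0.44 at resolution 1.0, −0.0920 with centred expression, −0.86 with each library on its own and −0.0436 in cluster 1 alone.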

Other observations

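The genes of the next paragraph and the values from cluster 1 alone were chosen only after the result was seen; the lists were fixed before.

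Within Icam1-like cells, genes of adipocyte commitment went both ways although their list median was −0.09 (percentile 16.1). Agt, the angiotensinogen gene, stood at 1.99 UPM in WT and 11.1 UPM in transgenic (log2 2.48, from 1.57 to 3.53), and at 2.24 in cluster 1 alone. Klf15, a factor of adipocyte differentiation, stood at 15.96 and 4.68 UPM (−1.77, from −2.35 to −1.22), and at −1.28 in cluster 1 alone. Dlk1, a preadipocyte factor that restrains adipogenesis, stood at 12.7 and 0.468 UPM (−4.76), but cluster 1 alone gave −1.55 and clustering each library on its own −0.28. The value of Dlk1 thus rests in part on cluster 9, which held 39 WT and 9 transgenic cells.

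TGF-beta and BMP signalling genes had a median of 0.25 (0.18 to 0.31, percentile 99.9) in Icam1-like cells, with Ccn2 at 0.84, Smad7 at 0.67 and Id1 at 0.62; 14 of 20 members were higher in the transgenic library. That median was 0.14 in cluster 1 alone and lay between 0.10 and 0.43 over the alternatives. Hypoxia and glycolysis genes stood at 0.18 (percentile 98.4) in the same cells, with 15 of 17 higher. In cluster 2, interferon-induced Ifit3b and Rsad2 stood at −2.23 and −1.88, and 27 of 29 interferon response members were lower. The fibro-inflammatory list stood at 0.25 (percentile 99.6) in cluster 2, opposite in sign to its value over all progenitors. None of these differences between classes was tested.

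Of the WT barcodes at 1000 or more UMIs, 1339 had too few genes, and haemoglobin held over 50% of the UMIs in 1275 of them (95.2%). The transgenic library had 1519 such barcodes, 1410 of them with mostly haemoglobin (92.8%). Both libraries had been treated with red cell lysis according to the labels. Cluster 10 combined haemoglobin with progenitor transcripts in 24 WT and 23 transgenic cells and was not used in the comparisons. In the barcodes with 50 or fewer UMIs, acinar genes held 5.04% of WT and 4.20% of transgenic UMIs.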
